A study of Homo sapiens with 11 samples.

How the data were processed

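RNA sequencing libraries of human thyroid tissue were labelled Tumor or Normal by disease state. Per the labels' protocols, polyadenylated RNA was purified from total RNA, fragmented, copied into double-stranded cDNA with an Illumina mRNA sample kit, size-selected on a gel, amplified by PCR and sequenced from both ends on a Genome Analyzer IIx. The protocol names no step that marks strand. The deposited table holds raw read counts per gene, 1 column per library, per the file headers and from its whole-number values. Per the submitters' processing notes, CASAVA 1.8, TopHat, SAMtools and bedtools were used with the genome build hg19, with no role given for each. The annotation, the rule for reads that map to several genes and the strand setting are not given in the sources used here, so genes with close copies, overlapping genes and antisense genes are uncertain. Between 55.0% and 58.5% of the counts from 1 to 20 in a library were even, more than an equal mix of even and odd counts would give, so the reads of a pair seem to have been counted singly.

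The labels list 11 samples, 6 tumour and 5 normal. Tumour replicate 5 was not analysed here, which leaves 5 against 5 where the design set before the data were examined had all 11. The table also holds 1 column of values that was matched to no sample; it repeats the values of tumour replicate 25 in every row and was not used. The table has 22513 rows, of which 3316 are 0 in every library. A symbol is shared by 99 rows, which were kept apart by adding the chromosome to the symbol. Gene positions are those of the deposited table in hg19. Their starts were counted from 0: of 18951 genes matched by symbol to a RefSeq table of assembly GRCh38.p14, 2531 had a length equal to end minus start and 275 had that length plus 1. Starts are therefore given with 1 added, and no position was taken from the RefSeq table.

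Counts were analysed in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 16445 genes. Libraries were scaled by the trimmed mean of M values (TMM), and tumour was compared with normal by the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, group as the only term). P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken from the test's F statistic. Expression is given as CPM on TMM-scaled libraries, with mean ± SD over 5 libraries, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 56.9%. Total counts per library ran from 70362488 to 193561642, and counting error at 5 CPM in the shallowest library was 5.33% with every read taken as independent and 7.54% with the reads of a pair counted singly, so the spread between libraries, not depth, set the precision.

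Before any values were seen, 24 gene lists with 441 members, the tests, the alternatives and the rule for named genes were fixed. The rule took the 12 genes with the largest increase and the 12 with the largest decrease among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups. From each list it took up to 4 members with the smallest adjusted p, or the first 1 where none was called, and it added 11 genes fixed by name. It gave 67 genes, of which 63 are reported as named genes; the other 4, and 1 further scaling of the libraries, are not reported here. Y-linked, XIST and antigen receptor genes were not named. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists, and again with an estimated correlation and with fry. Counts of called list members are given over all genes tested and adjusted over the list alone. A library apart from its group was found by Dixon's ratio of the gap to the range, with a chance of 5% per group.

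The gene test was checked on simulated data for this comparison: negative binomial counts were drawn for the 16445 genes with the means, dispersions and library sizes of the real libraries, and 200 genes were changed. The test recovered 0% of genes changed by 2-fold, 63.5% of those changed by 4-fold, 81.5% by 8-fold and 91.5% by 16-fold, with 0, 3, 8 and 2 false calls. Simulated genes were independent and each had the same dispersion in both groups. In the real libraries 82.2% of genes had a larger variance in tumour, so these rates need not hold there. With the members of a single list changed by 2-fold among the 24, camera called that list and 0 others; genes in that simulation were independent, unlike real genes.

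The alternatives fixed before the data were examined were DESeq2 size factors in edgeR, library size alone, DESeq2 1.42.0, limma-voom, no low-count filter beyond 1 count, a stricter filter of at least 50 counts in at least 5 libraries, a robust fit, the replicate number as a block, and leaving out each of the 10 libraries. Adjusted p-values that DESeq2 left undefined were not counted as calls. Alternatives added after seeing the data left out both libraries numbered 23, or took the mean of the immune markers or of the immediate early and heat shock genes as a covariate, and the spread between libraries was also recomputed under other settings.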

Results

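Polyadenylated RNA from thyroid tissue was sequenced to compare tumour tissue with tissue labelled normal, in a study of radiation-induced thyroid cancers that searched for kinase fusion oncogenes, in which a rearrangement joins a kinase gene to another gene. The comparison used 5 tumour and 5 normal libraries, each group numbered 22 to 26 in the labels, and the deposited values were read counts per gene for 22513 genes. Total counts ranged from 70709000 to 193561642 in the normal libraries and from 70362488 to 145744799 in the tumour libraries. The 2 libraries numbered 23 were the shallowest in each group, and every other library held at least 139047593 counts. In the shallowest library a level of 1 CPM (counts-per-million) corresponded to 70.4 counts. The thyroglobulin gene TG alone took 4.40% to 8.29% of the counts in the normal libraries and 2.41% to 10.3% in the tumour libraries. The labels do not say that the replicates came from separate donors, so the p-values measure the spread between these samples.

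The tumour libraries differed from one another more than the normal libraries did. The root mean square distance of a library from its group mean, over log2 CPM of the 16445 genes tested, averaged 0.985 in tumour and 0.589 in normal, and the smallest tumour distance, 0.714, exceeded the largest normal distance, 0.708. The difference of 0.396 had a two-sided p of 0.00794 when these distances were permuted between the groups, the smallest that the 252 splits allow. Group means were not recomputed for each split, so the p is approximate as a test of equal spread. Of the genes tested, 82.2% had a larger variance in tumour. The sodium iodide symporter gene SLC5A5, which carries iodide into thyroid cells, spanned 0.321 to 969 CPM across the tumour libraries and 30.6 to 452 CPM across the normal libraries. The first principal component held 32.9% of the variance and did not separate the groups, while the second held 24.6% and placed every normal library above every tumour library.

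**Figure D1:**
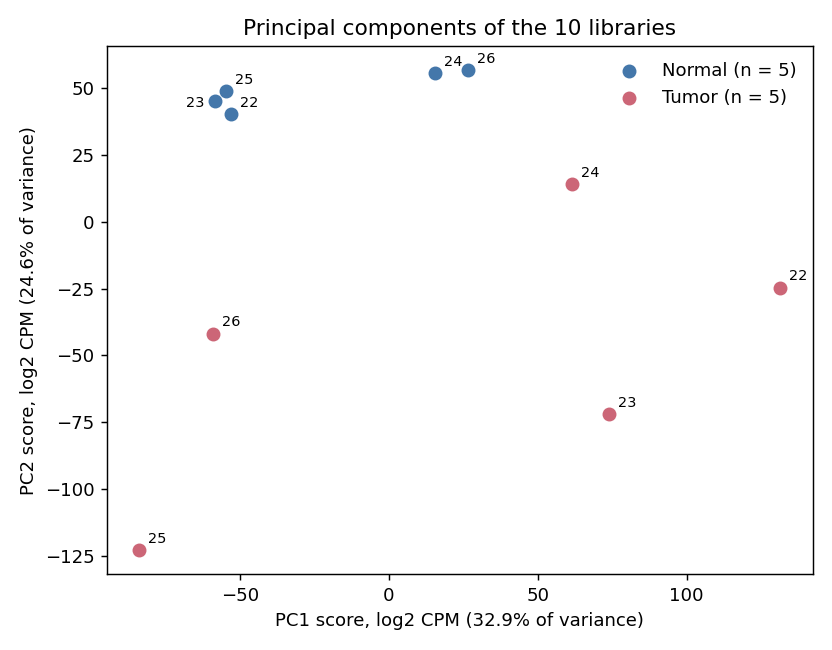
Principal component scores of the 10 libraries computed from log2 CPM, with PC1 (32.9% of the variance) on the horizontal axis and PC2 (24.6%) on the vertical axis; each point is a library, coloured by group (5 normal, 5 tumour) and marked with its replicate number. The normal libraries lie together at PC2 scores of 40.5 to 56.9, and the tumour libraries are spread between -123 and 14.2.

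The comparison of tumour with normal tissue called 79 genes changed, 65 higher and 14 lower in tumour. Among called genes with a mean of at least 5 CPM in tumour, the largest increases included genes of a cell adhesion protein, of neuronal receptor subunits and of a germ-line protein. CDH2, the gene of N-cadherin, a cell adhesion protein (chromosome 18, 25530930 to 25757445 in hg19), averaged 3.23 ± 2.93 CPM in normal and 116 ± 66.9 CPM in tumour (SD, n = 5 each), a log2 fold change of 5.17 ± 0.71 (SE; edgeR quasi-likelihood test, adjusted p = 0.0299). GABRB2 and GABRD, which encode subunits of the GABA-A receptor of neurons, rose by log2 fold changes of 6.13 and 4.22. KLHDC8A (chromosome 1, 205305648 to 205326039) rose from 0.591 ± 0.570 to 65.2 ± 49.1 CPM, with a log2 fold change of 6.77 ± 1.07. ESM1, which encodes a proteoglycan secreted by endothelial cells (chromosome 5, 54273695 to 54281414), rose from 0.417 ± 0.228 to 25.5 ± 27.4 CPM, and GDF15, a stress-responsive cytokine of the TGF-beta family, rose from 0.998 ± 0.528 to 18.8 ± 12.5 CPM.

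The other leading increases were NGEF at a log2 fold change of 5.56, FOLH1, a folate hydrolase also known as prostate-specific membrane antigen, at 5.38, SCEL, encoding the epithelial protein sciellin, at 4.13, PIWIL1, a germ-line protein that binds piRNAs, at 4.13, and SRCIN1, an inhibitor of SRC kinase, at 4.02. EEF1A2, a translation elongation factor, had a log2 fold change of 5.61, but it is a close copy of the very abundant EEF1A1, and FOLH1 also has a close copy, so reads may have been shared and both values are uncertain. The limit of 5 CPM left out HAPLN1 at 7.10 and ZNF560 at 5.75, among others, and both are named after their values were seen. The rule that picked the 12 genes also asked for no overlap between the groups, so each was higher in 5 of 5 tumour libraries by selection. Their adjusted p lay between 0.0299 and 0.0497, and the spread between tumours was wide, from 5.69 to 88.7 CPM for GABRB2.

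The 12 decreases that the rule took, at a mean of at least 5 CPM in the higher group, were smaller. HHIP, below that level and named after its values were seen, fell from 0.689 ± 0.461 to 0.0414 ± 0.0237 CPM, a log2 fold change of -4.01 (adjusted p = 0.0309). AIF1L, an actin-binding protein (chromosome 9, 133971863 to 133998539), fell from 433 ± 117 to 116 ± 40.9 CPM, a log2 fold change of -1.90 ± 0.29 (adjusted p = 0.0312). AGPAT4, an acyltransferase of phospholipid synthesis, was 4.22-fold lower in tumour, EMID1 was 3.50-fold lower, and HSD17B14, a steroid dehydrogenase, was 3.20-fold lower. BZRAP1, EBF4, RAB23, WWOX, MLLT1 and WBP5 had log2 fold changes of -1.495, -1.36, -1.28, -1.21, -1.14 and -1.01. ESD, which encodes an esterase that hydrolyses S-formylglutathione, changed least among the 12 but with little spread, from 141 ± 10.4 to 84.0 ± 3.88 CPM, a log2 fold change of -0.74 ± 0.10. ST7-AS1 was 4.10-fold lower, but it is antisense to ST7 and the counting was not stated to use strand, so its reads cannot be told from those of its partner. These 12 were also picked for no overlap between the groups.

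**Figure D2:**
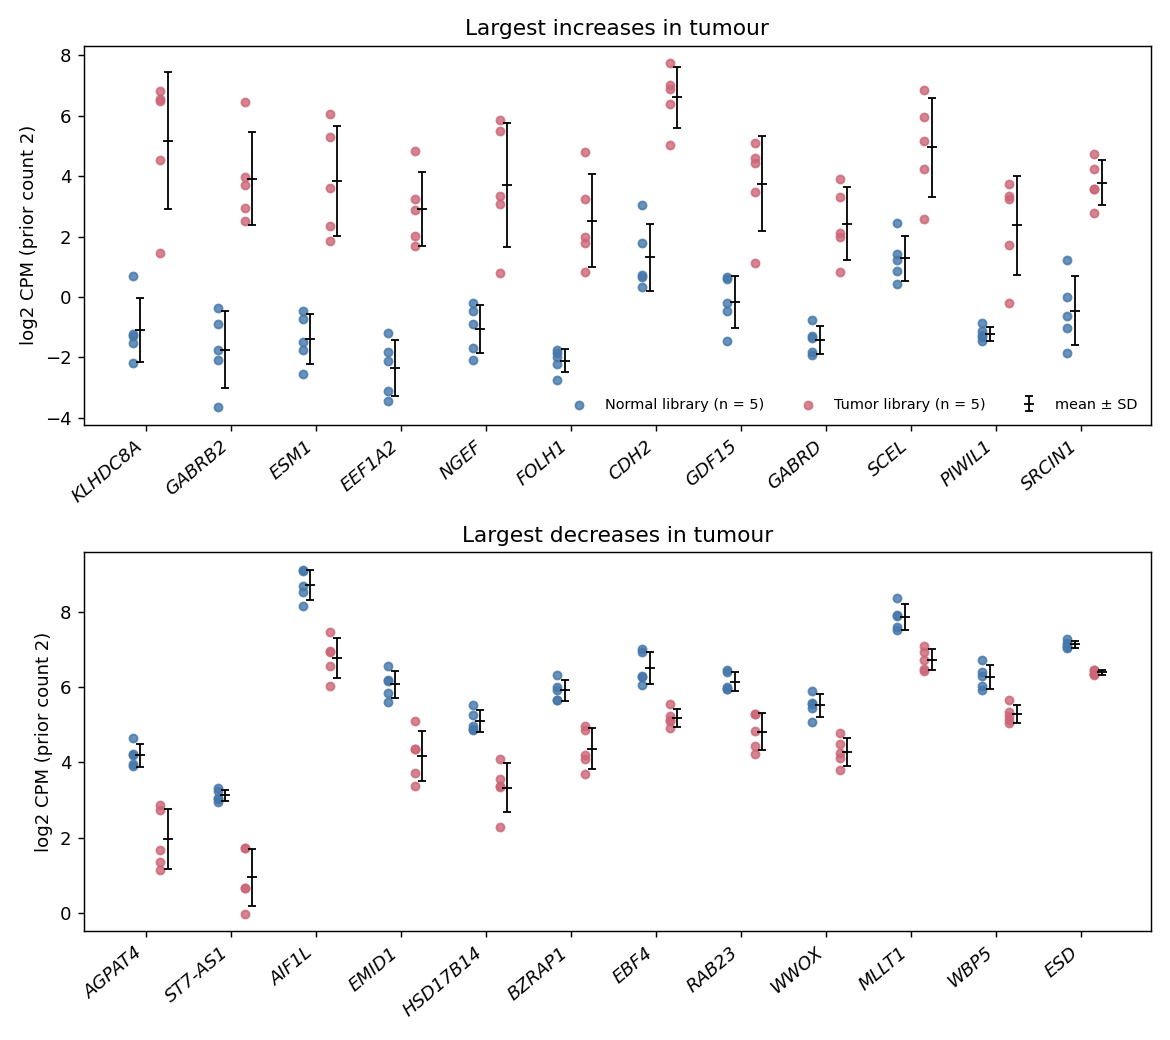
Expression of the 12 genes with the largest increases (top) and the 12 with the largest decreases (bottom) in tumour, among called genes with a mean of at least 5 CPM in the higher group. Values are log2 CPM with a prior count of 2. Each point is a library (blue normal, red tumour, 5 each) and the black bars give the mean ± SD. The 24 genes were picked for no overlap between the groups. For some of the genes that rose the tumour points are spread wider than the normal points. KLHDC8A ran from 2.71 to 114 CPM in tumour and from 0.206 to 1.60 CPM in normal. This did not hold for SRCIN1, at 2.77 to 4.73 in tumour and -1.84 to 1.23 in normal, in log2 CPM.

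The count of 79 came from edgeR's quasi-likelihood test on 16445 genes at an adjusted p under 0.05, and 72 of the genes changed by over 2-fold, 60 upward and 12 downward. At an unadjusted p under 0.05 the test held 3086 genes, and all 79 called genes, like 927 genes in all (5.64%, against 0.794% by chance), had no overlap between the groups. The smallest adjusted p was 0.0299, and the count moved with single libraries: edgeR called 0 genes without normal replicate 22, 23, 24 or 25 or tumour replicate 23, 4 without normal replicate 26, 24 without tumour replicate 22, 255 without tumour replicate 24, 390 without tumour replicate 25 and 276 without tumour replicate 26. DESeq2 called 1632 genes, including all 79, whereas edgeR called 0 without both libraries numbered 23 or with the mean of the immediate early and heat shock genes as a covariate, and 158 with the mean of the immune markers as a covariate. Limma-voom called 45 genes higher and 33 lower, against 65 and 14 with edgeR.

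Genes known to be raised in papillary thyroid cancer, the commonest thyroid carcinoma, had positive log2 fold changes for all 24 members tested, with a median of 3.16. GABRB2 and NGEF passed over all genes tested in edgeR, while DESeq2 called 17 members and limma-voom 0. Adjusted over the list alone, 21 members passed, none lower. Among those 21, LRP4, a receptor of the LDL receptor family, averaged 7.83 CPM in normal and 226 CPM in tumour, and MET, the receptor of hepatocyte growth factor, averaged 75.5 ± 21.2 and 304 ± 196 CPM (SD, n = 5). The list mean in log2 CPM was 7.44, 8.56 and 6.39 in tumour replicates 22, 23 and 24, but 4.10 and 3.39 in replicates 25 and 26, within the normal libraries (2.85 to 4.53), and LRP4 was at 15.0 and 16.9 CPM in those 2, against up to 14.5 CPM in normal. For LRP4 and MET the edgeR adjusted p over all genes was 0.0758 and 0.0783. Genes known to be lowered in papillary thyroid cancer had negative log2 fold changes for all 20 members, with a median of -1.09, and none passed over all genes or adjusted over the list alone, with 8 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma-voom. Their list mean in log2 CPM was 4.48, 3.87, 6.50 and 6.10 in tumour replicates 22, 23, 24 and 26, but 7.18 in replicate 25, within the normal libraries (6.85 to 7.89). The member with the smallest p was the metallothionein gene MT1F, at a log2 fold change of -1.496 ± 0.47 (adjusted p = 0.146), and its reads can be shared with its close paralogs. In camera, which compares a list with the other genes, the adjusted p was 2.31e-14 for the raised genes and 4.73e-11 for the lowered genes, and with an estimated correlation the adjusted p was 0.312 for each. The median of the raised genes was 2.04 without both libraries numbered 23 and 1.86 with limma-voom, which gave the lowered genes a median of -1.84.

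Of the targets of p53, the transcription factor activated by DNA damage, 3 rose in tumour over all genes tested: BBC3 and EDA2R, which act in cell death, and PHLDA3, an inhibitor of AKT signalling. BBC3 (chromosome 19, 47724079 to 47736023) averaged 2.50 ± 0.58 CPM in normal and 13.5 ± 5.31 CPM in tumour, a log2 fold change of 2.43 ± 0.34 (adjusted p = 0.0299). PHLDA3 rose 4.01-fold and EDA2R 3.67-fold, each above every normal library in 5 of 5 tumour libraries. Of the 22 members tested, 20 had positive log2 fold changes, with a median of 0.61, and 11 were higher and 1 lower when adjusted over the list alone. The 11 included ZMAT3, at 29.1 CPM in normal and 91.6 CPM in tumour, and MDM2, the ubiquitin ligase that degrades p53, at 70.8 and 135 CPM. The exception was GADD45A, a DNA damage response gene, at a log2 fold change of -2.05. The list mean in log2 CPM was 5.61, 5.29 and 5.39 in tumour replicates 22, 23 and 24, and 4.78 and 4.81 in replicates 25 and 26, within the normal libraries (4.13 to 4.95). MDM2 and GADD45A were named after their values were seen. Camera gave the list an adjusted p of 6.83e-09, which was 0.312 with an estimated correlation.

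Genes of ERK pathway output, which growth factor signalling through BRAF and MEK switches on, moved in part. SPRY4, a feedback inhibitor of the pathway, rose from 15.95 ± 4.32 to 49.3 ± 14.8 CPM (log2 fold change 1.63 ± 0.25, adjusted p = 0.0345), and the transcription factor gene ETV4 rose from 4.72 ± 2.30 to 31.1 ± 16.8 CPM (2.72 ± 0.46, adjusted p = 0.0382). Of the 24 members, 6 were higher and 1 lower when adjusted over the list alone. The lower one was MAFF, a stress-induced transcription factor, at a log2 fold change of -3.43 (-0.88 with the immediate early mean as a covariate), with normal values from 16.5 to 560 CPM overlapping the tumour values of 6.001 to 36.5 CPM. The 6 included HMGA2, a chromatin protein, at 6.13 (2.66 with limma-voom) but with tumour values from 0 to 135 CPM. The list mean in log2 CPM was 5.50, 5.98 and 5.47 in tumour replicates 22, 23 and 24, 3.14 in replicate 25, below every normal library (3.64 to 5.23), and 3.90 in replicate 26, within them. The median log2 fold change was 0.97, and the camera adjusted p was 0.00262, or 0.630 with an estimated correlation. Without both libraries numbered 23 the median was 0.45 and the adjusted p 0.239, which ended the call.

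Cell cycle genes were positive in all 22 members tested, with a median log2 fold change of 1.497. None passed over all genes in edgeR, where 14 were at an unadjusted p under 0.05, and 14 were higher and none lower when adjusted over the list alone, while DESeq2 called 13 and limma-voom 1. BUB1B, a mitotic checkpoint kinase, averaged 0.704 ± 0.384 CPM in normal and 2.69 ± 1.21 CPM in tumour (log2 fold change 1.93 ± 0.47, adjusted p = 0.0928), and was above every normal library in 5 of 5 tumour libraries. The list mean in log2 CPM was 1.74 in tumour replicate 25, within the normal libraries (-0.0717 to 1.99), and 2.13 to 3.23 in the other tumour libraries. Camera gave the list an adjusted p of 4.55e-12, which was 0.312 with an estimated correlation, and the median ran from 0.94 to 1.78 with 1 library left out.

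Among endothelial markers, PLVAP, a component of the diaphragms of fenestrated capillaries (chromosome 19, 17462264 to 17488137), rose from 97.4 ± 24.6 to 250 ± 40.7 CPM, and FLT1, a receptor of the VEGF growth factors (chromosome 13, 28874483 to 29069265), rose from 27.4 ± 7.68 to 71.3 ± 16.4 CPM. Their log2 fold changes were 1.36 ± 0.20 and 1.38 ± 0.23, with adjusted p of 0.0312 and 0.0356. Of the 15 markers, 5 were higher and none lower when adjusted over the list alone, among them KDR, the other main VEGF receptor, at 0.93 and VWF, the von Willebrand factor gene, at 1.59. Only 8 of the 15 were positive, and the median was 0.19. The camera adjusted p was 0.0201, or 0.312 with an estimated correlation, and without tumour replicate 23 the median was -0.04 and the adjusted p 0.0736, and the call also ended without tumour replicate 24 (0.0601), without both libraries numbered 23 (0.190) and with limma-voom (0.122).

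Smooth muscle and pericyte markers split, with 4 of 12 higher and 4 lower when adjusted over the list alone. The member with the smallest p was LMOD1, an actin filament protein of smooth muscle, at 185 ± 90.5 CPM in normal and 28.1 ± 22.8 CPM in tumour. The list's median log2 fold change was -0.75, and camera gave an adjusted p of 0.0910 (0.630 with an estimated correlation), which was under 0.05 without normal replicate 22 (0.0478) or 25 (0.0154) or tumour replicate 24 (0.00321) and with the immune mean as a covariate (0.0241). Adipocyte markers also split, with 2 of 10 higher and 2 lower over the list alone. LPL, a lipase of lipoprotein uptake, had a log2 fold change of 3.25 ± 0.74 (adjusted p = 0.0821). The adipocyte median was 1.69 and the mean 1.03, while camera's direction was down, with an adjusted p of 0.993. A single library set that median: without tumour replicate 25, whose list mean was 2.59 in log2 CPM against -1.50 to 0.0446 in the other tumour libraries, it was -1.01. Skeletal muscle markers had a median of 0.31 (0.12 to 0.60 with 1 library left out) and a mean of 0.12 against a camera direction of down (adjusted p = 0.779), and TNNT3, a troponin, had the smallest p, at a log2 fold change of -2.75 (-4.65 with limma-voom).

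Matrix proteases and inhibitors had a median log2 fold change of 1.20, with 6 of 16 members higher and none lower when adjusted over the list alone, KLK10, a kallikrein protease, first among them at 6.996 ± 1.92 (3.39 with limma-voom). KLK10 was at 102, 203 and 19.8 CPM in tumour replicates 22, 23 and 24, and at 0.0224 and 0.328 CPM in replicates 25 and 26, and the list mean was above every normal library only in the first 3. Camera gave an adjusted p of 0.0133 (0.630 with an estimated correlation). Leaving out 1 library moved the median from 0.56 to 2.29, and the call ended without tumour replicate 22 (adjusted p = 0.0612), without both libraries numbered 23 (0.207) and with limma-voom (0.0537). Keratins and epithelial junction genes had a median of 0.65 and 3 of 21 members higher over the list alone. Their camera adjusted p was 0.0412 (0.630 with an estimated correlation), and the call ended without normal replicate 22 (0.0582) or tumour replicate 23 (0.174) or 24 (0.0601), without both libraries numbered 23 (0.298) and with limma-voom (0.1602). Their median ran from 0.29 to 0.82 with 1 library left out. Extracellular matrix genes had a median of 0.48 with 16 of 20 members positive and none past either threshold in edgeR, while DESeq2 called 2 higher, and LOXL2, an enzyme that crosslinks collagen, had the smallest p at 1.81 ± 0.47. The list adjusted p was 0.349 in camera, and 0.0135 without tumour replicate 25, and the median ran from 0.21 to 0.70 with 1 library left out.

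Immune markers varied between libraries of both groups. The mean log2 CPM of the T cell, B cell and myeloid markers was 1.36 ± 2.16 in normal and 1.88 ± 2.46 in tumour (SD, n = 5; two-sided exact permutation p = 0.595), and it was above 3 in normal replicates 24 and 26 and in tumour replicates 22 and 24. Myeloid markers had a median log2 fold change of 1.25 (16 of 17 positive) and a camera adjusted p of 0.00469, and class II HLA antigen presentation genes a median of 1.28 (12 of 12 positive) and 0.00890. With an estimated correlation both were 0.630. T cell markers had a median of 0.49 and a camera adjusted p of 0.993, and B cell and plasma cell markers 1.29 and 0.404. Without tumour replicate 22 the myeloid, T cell and B cell medians turned to -0.05, -0.92 and -0.67, and neither the myeloid nor the HLA call held (adjusted p = 0.161 and 0.126); the HLA median was then 0.45, and DESeq2 did not hold the HLA call (0.0617). Interferon response genes had a median of 0.25 (0.0520 to 0.60 with 1 library left out) and a camera adjusted p of 0.584, and were called with the immediate early mean as a covariate (median 0.84, adjusted p = 0.00347). No member of these 5 lists passed over all genes or adjusted over the list alone in edgeR. The members with the smallest p were CD1A of dendritic cells at a log2 fold change of 2.56 (1.96 to 3.47 with 1 library left out), HLA-DMB at 0.80 (0.20 to 1.02), CD4 at 1.36 (0.42 to 2.09), BLK of B cells at 1.98 (0.90 to 2.70) and the interferon-induced GBP1 at -2.56 (-2.98 to -1.25, and -0.43 with the immediate early mean as a covariate). The HLA genes are a family with similar copies, so their values are uncertain.

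Immediate early and heat shock genes, which respond within minutes to stimulation and tissue handling, had negative log2 fold changes for 17 of 20 members, with a median of -1.49. None passed over all genes in edgeR, and NR4A1, chosen after its values were seen, and NR4A3 were lower when adjusted over the list alone, while 8 members were at an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. NR4A3, a nuclear receptor, averaged 218 ± 248 CPM in normal and 6.64 ± 8.499 CPM in tumour (log2 fold change -5.03 ± 1.12, adjusted p = 0.0809). The mean log2 CPM of the list was 8.37 ± 1.13 in normal and 6.89 ± 1.12 in tumour, and the groups overlapped (two-sided exact permutation p = 0.0873). The camera adjusted p was 3.18e-06, or 0.552 with an estimated correlation. HSPA1A and HSPA1B, 2 members of the list, are near-identical copies.

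Red cell markers, 4 in number, had a median of -1.28 with no member past either threshold in edgeR, while DESeq2 called 1 lower, and the beta-globin gene HBB had a log2 fold change of -1.64 ± 0.56 (adjusted p = 0.166; -0.94 with the immediate early mean as a covariate). The list adjusted p in camera was 0.0201 (0.461 with an estimated correlation, 0.0812 and 0.0749 without tumour replicate 22 or 26, 0.0921 with DESeq2, 0.0767 without the low-count filter and 0.0847 with the immediate early covariate), and the list includes the near-identical HBA1 and HBA2. C cell and parathyroid markers, which report the hormone-secreting cells beside the follicles, had a median of -1.91 over 7 members, of which 2 were positive: CALCB at 0.15 and CHGB at 3.31, both named after their values were seen. The list means overlapped, with normal replicate 26 at -1.86 and tumour replicate 24 at 0.60 in log2 CPM. SYP, encoding the vesicle protein synaptophysin, was lower over the list alone, at -1.72 ± 0.37, and the camera adjusted p was 0.00469 (0.460 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had a median of 0.24 and a camera adjusted p of 0.117, and no member passed over the list alone; the adjusted p was 0.0466 without normal replicate 23, 0.00864 without tumour replicate 24, 0.0274 without both libraries numbered 23 and 0.0369 with the immune covariate, and the median ran from 0.0527 to 0.33 with 1 library left out. Glycolysis and hypoxia genes had a median of 0.27 (0.0942 to 0.40 with 1 library left out) and a camera adjusted p of 0.230, and HK2, a hexokinase, was higher over the list alone, at 46.4 CPM in normal and 101 CPM in tumour.

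Camera with a preset correlation of 0.01 called 13 of the 24 lists, 9 higher and 4 lower, and with an estimated correlation it called none (smallest adjusted p 0.312). In 99 other splits of the same libraries into 5 and 5, camera called a median of 10 lists. Fry's directional test called the cell cycle, p53 and endothelial lists, each at an adjusted p of 0.0456, and its mixed test called 11. In the 20 lists with no member called by edgeR over all genes, 87 of 328 members were at an unadjusted p under 0.05, DESeq2 called 51 and limma-voom 1.

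**Figure D3:**
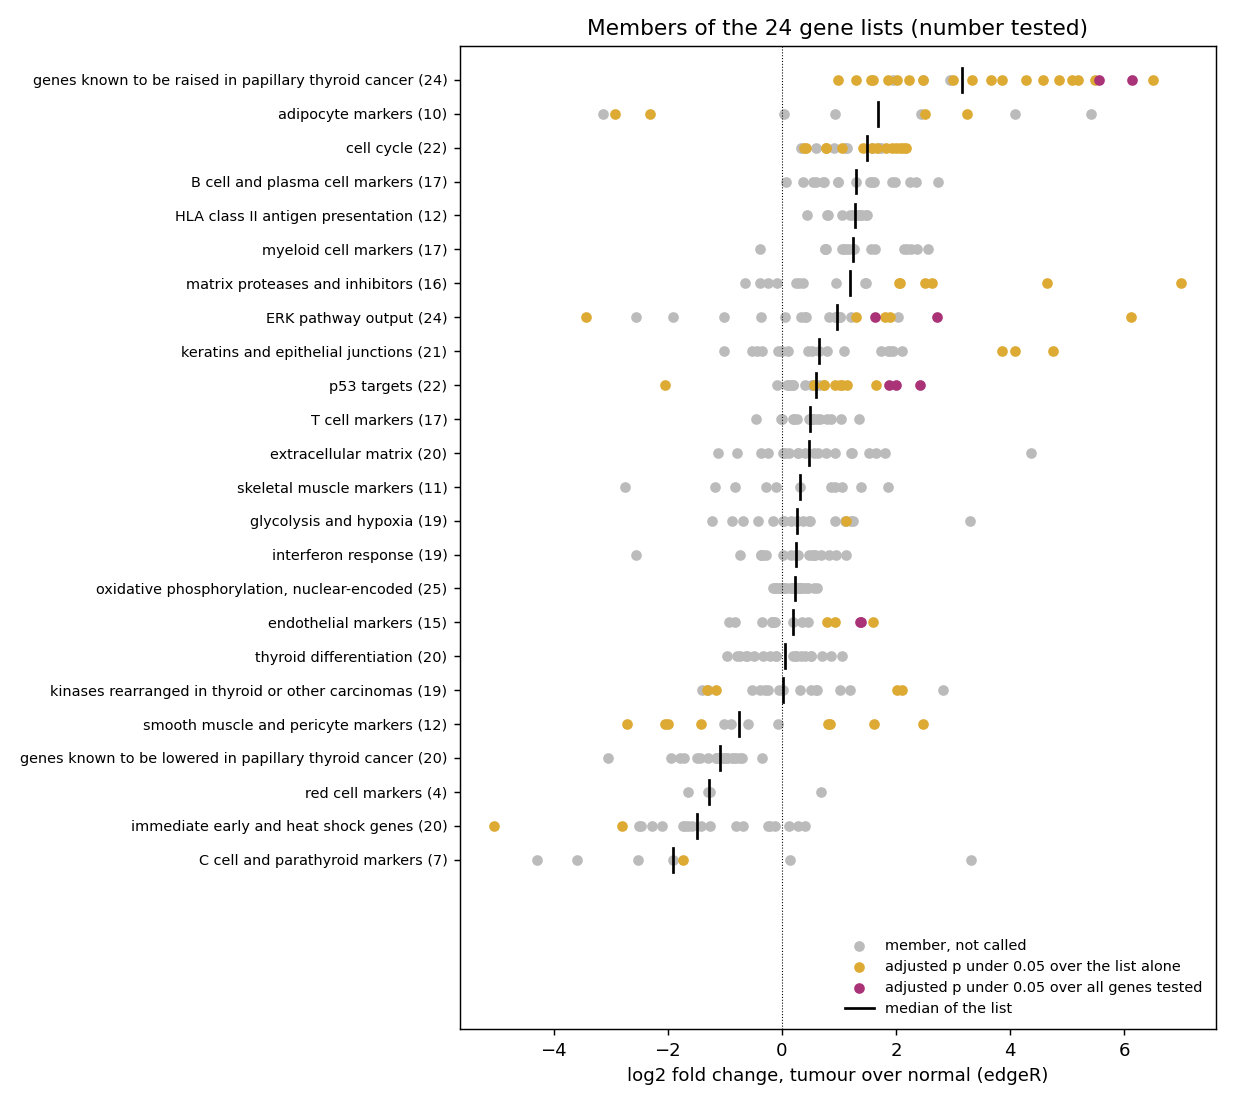
Log2 fold change of tumour over normal for each tested member of the 24 gene lists, with lists on the vertical axis (number of members in brackets) and log2 fold change on the horizontal axis; black bars are list medians, and colour shows whether a member passed an adjusted p of 0.05 over all genes tested, over the list alone, or neither. The list of genes raised in papillary thyroid cancer sits wholly above 0 with a median of 3.16, and the list of genes lowered in it wholly below 0 with a median of -1.09.

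Thyroid differentiation genes did not pass in edgeR over all genes or adjusted over the list alone, and 10 of 20 were positive. Only 1 gene was at an unadjusted p under 0.05 and DESeq2 called 1: IYD, the enzyme that recovers iodide from iodotyrosines, was below every normal library in 5 of 5 tumour libraries, at 2394 ± 507 CPM in normal and 1235 ± 347 CPM in tumour (log2 fold change -0.95 ± 0.24, adjusted p = 0.103). The list's median was 0.05 and its mean 0.01, camera's direction was down (adjusted p = 0.253). Camera called the list lower without tumour replicate 26 (median -0.244, adjusted p = 0.0294), without normal replicate 26 (-0.0825, 0.0424) and with the immediate early mean as a covariate (-0.192, 0.0326), and the median was -0.03 when libraries were scaled by library size alone. TG averaged 64190 ± 16126 CPM in normal and 55669 ± 33317 CPM in tumour (adjusted p = 0.858). The thyroid transcription factor gene PAX8 had a log2 fold change of -0.32 ± 0.38 and SLC5A5 of 0.25 ± 1.64, the last turning to -3.51 with limma-voom. SLC5A5 was below every normal library in 3 of 5 tumour libraries and above every normal library in 1, tumour replicate 26, at 969 CPM. Without that library its log2 fold change in edgeR was -3.35 (adjusted p = 0.225).

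Kinases that are rearranged in thyroid or other carcinomas were the genes closest to the study's question. None of the 19 tested passed over all genes in edgeR, with 6 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma-voom, and 2 were higher and 2 lower when adjusted over the list alone. The higher ones were MET and ALK, a receptor kinase, which averaged 0.378 ± 0.158 CPM in normal and 1.627 ± 1.495 CPM in tumour (log2 fold change 2.10 ± 0.60, or 1.34 to 2.36 with 1 library left out, adjusted p = 0.124). The lower ones, FGFR2 and FGFR4, were named after their values were seen, at -1.31 and -1.16. RET had a log2 fold change of -1.29 ± 0.61 (-0.81 without both libraries numbered 23), NTRK3 of 2.82 ± 1.16 (1.33 with limma-voom) and BRAF of 0.32 ± 0.27 (0.13 to 0.46 with 1 library left out). NTRK3 was above every normal library in 3 of 5 tumour libraries, at up to 6.19 CPM against up to 0.978 CPM in normal. CLIP2, a gene studied in radiation-associated thyroid cancer, had a log2 fold change of -0.07 ± 0.34 (adjusted p = 0.931). The kinase list's median was 0.01 and its mean 0.24, against a camera direction of down (adjusted p = 0.714), and its median was -0.08 with library size alone.

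A rearrangement that activates a kinase can differ from tumour to tumour, so each kinase gene was also checked for a single tumour library apart from the other 4. Among the 19 genes, 2 had such a library by Dixon's ratio of the gap to the range of log2 CPM, where chance gives 0.95, and 0 did among the normal libraries. Both were low in that library, and both were named after their values were seen. NTRK2, a neurotrophin receptor, was at 3.42 CPM in 1 tumour library and at 59.3 to 169 CPM in the other 4 (ratio 0.731). FGFR1 was at 15.7 CPM against 43.4 to 55.6 CPM (ratio 0.803). Without the low-count filter 20 kinase genes were measured, and 3 had a library apart, the third being ROS1, also named after its values were seen.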

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

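Among the 63 named genes, 126 groups of 5 libraries were checked for a single library far from the rest, and 5 were found where chance gives 6.3. In tumour, FLT1 was at 99.8 CPM in replicate 26 and at 59.5 to 68.7 CPM in the others (gap over range 0.723), and NR4A3 was at 21.8 CPM in replicate 24 and at 2.54 to 3.54 CPM in the others (0.847). In normal replicate 26, MT1F was at 115 CPM against 413 to 542 CPM in the others (0.825). HBB was at 118 CPM in normal replicate 24 against 32.4 to 41.7 CPM (0.805), and BBC3 was at 1.53 CPM in normal replicate 23 against 2.47 to 2.97 CPM (0.724).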

How the results depend on the processing

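The alternatives that left out both libraries numbered 23 or added a covariate, and all settings of the spread, were chosen after seeing the data. All 31 called named genes kept their direction in every setting, and of all 63 named genes 59 did. As all 79 called genes had no overlap between the groups, leaving out a library could hardly turn their direction. Their kept direction is therefore no support for the calls. Scaling by DESeq2 size factors called 89 genes and by library size alone 70, the 2 other filters 69 and 91, the robust fit 71 and limma-voom 78, of which 58 were among the 79. Limma-voom split them into 45 higher and 33 lower. DESeq2 called 1632 genes, 1038 higher and 594 lower, 1147 of them by over 2-fold. With the immune covariate edgeR called 158, with 112 higher, 46 lower and 137 by over 2-fold. The cause was not tested.

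Without both libraries numbered 23, and with the immediate early covariate, edgeR called 0 genes in either direction or over 2-fold, with 2097 and 1682 genes at an unadjusted p under 0.05; the first setting has fewer libraries. Leaving out 1 library gave 0 to 390 changed genes, 0 to 308 higher, 0 to 120 lower and 0 to 327 by over 2-fold. The counts were 0 without normal replicate 22, 23, 24 or 25 or tumour replicate 23 (2412 to 2784 genes at an unadjusted p under 0.05), 4 without normal replicate 26, 24 without tumour replicate 22, 255 without tumour replicate 24, 390 without tumour replicate 25 and 276 without tumour replicate 26. With the replicate block 0 genes were called in either direction or over 2-fold (2355 at an unadjusted p under 0.05). The labels do not say that a shared number marks a shared donor. The deviations of same-numbered libraries from their group means correlated at -0.34 to 0.37, over 0.1 in 3 of 5 pairs. Of the libraries, 1 of 5 normal and 3 of 5 tumour correlated best with their own number. The numbers were not taken as pairs, but such correlations cannot exclude a shared donor, so a pairing stays possible.

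Camera called 13 lists, 0 with an estimated correlation, and fry 3. The replicate block ended the keratin call (adjusted p = 0.0529) and kept the other 12. Calls of 7 of the 13 lists held whichever library was left out. A list's direction was read from the sign of its median, a choice made after seeing the data, as camera's own direction can differ. The medians of 17 of the 24 lists kept their sign in every setting. The thyroid differentiation median turned to -0.0334 with library size alone, -0.38 with limma-voom, -0.36 with the replicate block, -0.0629 with the immune and -0.19 with the immediate early covariate (-0.244 to 0.0903 with 1 library left out). The kinase median turned to -0.0781 with library size alone, -0.34 with limma-voom, -0.00602 with the stricter filter and -0.19 with the block (-0.0145 to 0.144). The T cell median turned to -0.19 with limma-voom, -0.78 with the block and -0.84 with the immune covariate (-0.92 to 1.13), the B cell median to -0.0941 with the immune covariate (-0.67 to 2.02), the adipocyte median to -0.58 with the block (-1.01 to 1.93) and the endothelial median to -0.00765 without both libraries numbered 23 (-0.0446 to 0.276); the myeloid median ran from -0.0461 to 2.20. SLC5A5 turned to -3.51 with limma-voom, -4.65 with the block, -0.51 with the immune and -1.66 with the immediate early covariate (-3.35 to 0.99). CLIP2 turned to 0.0214 with the immediate early covariate (-0.34 to 0.13), and TG to 0.0656 and PAX8 to 0.0589 without both libraries numbered 23. None of these genes was called. The spread was wider in tumour in every setting run, by 0.274 to 0.458 with 1 library left out.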

Other observations

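Smooth muscle and pericyte markers moved in both directions when adjusted over the list alone. The 4 lower members were LMOD1, CNN1, MYH11 and ACTG2, with log2 fold changes of -2.72, -2.04, -2.00 and -1.42, and the 4 higher were CSPG4, MCAM, NOTCH3 and RGS5, with 2.47, 1.62, 0.84 and 0.80. The other 4 did not pass: TAGLN was at -1.01, SYNPO2 at -0.90, CASQ2 at -0.60 and ACTA2 at -0.06. In the adipocyte list, LPL and GPD1 were higher at 3.25 and 2.51, and FABP4 and CIDEC lower at -2.30 and -2.93. None passed over all genes tested in edgeR, and apart from LMOD1 and LPL these genes were named after their values were seen.

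In 100 of the 126 splits of the libraries into 5 and 5, only the real one (1) gave as many as 79 changed genes, 65 in one direction or 72 by over 2-fold. The highest of the others was 22 for each. Chance can be excluded for these counts only with the libraries taken as independent, unpaired and of equal spread in both groups. Equal spread did not hold (mean distance 0.985 in tumour and 0.589 in normal). The splits therefore cannot tell a change in mean from a difference in spread. As many as 14 genes in one direction came from 2 splits, so chance can be excluded there on the same terms, although the highest other count, 22, was larger. The labels do not say whether a shared number marks a pair, and with the replicate block edgeR called 0 genes. Splits that keep such pairs were not run, so with pairs these counts would stay open to chance. Chance cannot be excluded for the count of lists, since 26 of 100 splits gave 13 or more called lists, and the highest other gave 18. For the p53 list only the real split gave a camera p as small, but 4 of 100 splits gave a median as far from 0, the largest other being 0.83 against the real 0.61. A camera p as small came from 5 splits for the cell cycle list, 6 for the endothelial list, 9 for the genes lowered and 15 for the genes raised in papillary thyroid cancer. For the remaining called lists it came from 19 splits (C cell and parathyroid markers) to 53 (myeloid markers), with 39 for ERK pathway output.

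The p53 targets had a median log2 fold change of 0.61 in tumour (0.56 to 0.74 with 1 library left out), with 3 of 22 passing over all genes tested and a list adjusted p of 0.312 in camera with an estimated correlation, and the list means of tumour replicates 25 and 26, 4.78 and 4.81 in log2 CPM, lay within the normal libraries (4.13 to 4.95). Immune cells were argued against only as far as the mean of all immune markers records them. With that mean as a covariate the median was 0.72 (0.58 to 0.73 with 1 library left out), where a cause needs a median within 0.2 of 0. The myeloid list was still called with that covariate (camera adjusted p = 2.34e-05). The covariate thus did not remove the myeloid difference, and myeloid cells stay open. Of the 51 immune markers, 0 are in the p53 list and 46 averaged 1 CPM or more in normal tissue; C1QB and LYZ of myeloid cells, named after their values were seen, averaged 25.1 and 76.0 CPM in normal and 130 and 129 CPM in tumour. Handling, as far as the immediate early and heat shock genes record it, was argued against for the list median only. That median was 0.81 with their mean as a covariate (0.62 to 0.96). The mean itself differed between the groups by -1.48 (tumour minus normal), so the covariate separates handling from group only in part. The shallow libraries were argued against by a median of 0.61 without them (0.48 to 0.71). In both of these settings edgeR called 0 genes, so the calls of BBC3, PHLDA3 and EDA2R did not hold. No biological explanation was tested, since p53 activity was not measured here and the labels mark no group of tumours without radiation exposure. RNA quality also stays open as untested.

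PLVAP and FLT1 were higher in tumour by log2 fold changes of 1.36 and 1.38. The test of endothelial cell number was chosen after the result was seen. If a larger number of endothelial cells were the whole cause, all endothelial markers would rise by about as much. The median over the 15 was 0.19, below 1.36 by more than the SD of 0.79 over the markers. PLVAP and FLT1 were chosen as the called markers, however. Such a gap is favoured by that choice, so the test cannot decide on endothelial cell number. All 15 averaged 1 CPM or more in normal tissue, and 0 are in another list. ESAM, the most abundant of them in normal tissue and named after its values were seen, was at 204 CPM in normal and 183 CPM in tumour. A larger number of endothelial cells therefore stays open. A change in their state, or in their kinds, may also remain and was not tested.

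Tumour libraries lay farther from their group mean than normal libraries. Immune cells were argued against as the cause: without the 1658 genes that follow the immune markers, at an absolute correlation over 0.7, the difference in mean distance was 0.442 (0.297 to 0.496 with 1 library left out). The shallow libraries were argued against by a difference of 0.420 without them (0.258 to 0.487). Differences between the tumours themselves may account for it, and so may differences in the share of tumour cells, which were not tested.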
